A study of Homo sapiens with 12 samples.

How the data were processed

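RNA of 12 samples of the L428 cell line was measured on Illumina HT-12 arrays, 3 samples in each of 4 groups (control, 25 nM ixazomib, 71.25 nM ixazomib and ixazomib-resistant), per the labels. Groups were taken from sample titles. The columns of array signals carry the numbers 1 to 12 and a group, so each array is known by its group and number and was not tied to a replicate number of the labels. The labels' protocols name RNeasy extraction and a biotin labelling kit.

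The deposited table of signals holds a mean bead intensity per probe on a linear scale, neither background subtracted nor normalized between arrays, and a detection p-value per probe in 770 steps, as the deposited values show. The scanner software is not given in the sources used here. The authors' processed values are intensity values on a linear scale; per the series' design text they were corrected through housekeeping genes and quantile normalized, and genes were then tested by the methods' one-way test at a false discovery rate under 0.05. Each column of the authors' values had its highest rank correlation (0.99974 to 0.99999) with a signal column of its own group. The column medians were 104.4, 104.6 and 104 for control replicates 1 to 3, 104, 104.3 and 104.8 at 25 nM, 104.3, 103.9 and 104.3 at 71.25 nM, and 104.1, 104.3 and 104.4 in resistant cells. The scale was linear and no centring was seen; with 1 colour there is no ratio and no direction, and which housekeeping genes the authors used stays unknown.

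Mean signals per array ran from 293.2 to 400.5, and 36.2% to 39.8% of 47227 probes were detected at p under 0.05. Signals were background corrected with limma's normexp model, with the negative-control mean and spread inferred from the detection p-values and an offset of 16, then quantile normalized and taken to log2 (limma 3.58.1 in R 4.3.3; plots with matplotlib 3.10.9 and numpy 2.4.6). A probe was kept if it was detected on at least 3 of the 12 arrays, whatever their group, which left 20414 probes. Gene symbols came from the deposited table. Of its probes 3270 had no symbol and 54 had a symbol turned into a date, and 1195 kept probes without a symbol named no gene. Of 31303 symbols, 17760 are current and 3283 are older names in a RefSeq gene table of assembly GRCh38.p14, which was used for names only. Symbols are printed as deposited. Each gene was represented by its brightest kept probe, giving 14953 genes, of which 3343 had several kept probes. Of the 14953, 408 share a current gene with another, so some genes are counted more than once. Probes of a gene were called in opposite directions in 14 genes at 25 nM, 35 at 71.25 nM and 40 in resistant cells against control, and in 16 in resistant cells against 71.25 nM.

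Limma's linear model with 1 mean per group was fitted to all 12 samples (8 residual and 5.54 prior degrees of freedom), because the design text describes 1 one-way model. Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over all kept probes, and an adjusted p under 0.05 was called a change. Each adjusted p of a gene is from this model. Comparisons were each of the 3 groups against control, 71.25 nM against 25 nM, and resistant cells against 71.25 nM. A gene not detected on any array of a group was given as a bound: the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the gene's own, in normalized log2 values.

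There were 29 gene lists: proteasome, immunoproteasome, ubiquitin and autophagy, heat shock, ATF4, unfolded protein, NRF2, metallothioneins, MYC targets, DNA damage and checkpoint, S phase, G2/M, p53 targets, apoptosis regulators, NF-kB targets, Hodgkin cell, B cell, T cell, myeloid, and stromal and epithelial markers, MHC class I and II, interferon response, cholesterol synthesis, glycolysis and hypoxia, drug efflux, histones, cytosolic ribosomal proteins and oxidative phosphorylation. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 29 lists of a comparison, with camera with an estimated correlation and with fry as alternatives. At 25 nM 12 lists passed, 10 of them with an estimated correlation as well. At 71.25 nM these counts were 11 and 9, and in resistant cells 21 and 15. Between doses they were 9 and 3, and in resistant cells against 71.25 nM 17 and 12. A list adjusted p given without further remark is from the preset correlation. With an estimated correlation the adjusted p of each called list was larger, also where the call was kept. The very small list values therefore depend on the preset.

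Groups, tests, lists and alternatives other than those named as chosen after seeing the data were set before the data were examined. So was the rule for named genes: MYC, CHEK1 and PSMB5 in each comparison; the 10 largest rises and 10 largest falls among called genes without overlap between the groups in comparisons against control, and 5 each in the other comparisons; and up to 4 called members of each list by size, or up to 2 as values where none was called. Genes without an official symbol and those linked to sex were left out of the named genes. From these the text names a part, and some are not reported here.

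The gene test and the list test were checked on simulated data for 14953 genes with the same sample numbers. For the gene test, 67 genes were changed by 0.5 (log2), 67 by 1 and 66 by 2 in each comparison. For 25 nM against control, 38.8% of genes changed by 0.5 (log2) were recovered, 98.5% of those changed by 1 and 100% of those changed by 2, with 5.39% false calls. For 71.25 nM against control the values were 26.9%, 94% and 100%, with 7.55% false calls. For resistant cells against control the values were 34.3%, 100% and 100%, with 8.24% false calls. The share of false calls thus lay above the adjusted p threshold of 0.05 in each comparison against control. In the measured data 27%, 39.06% and 47.13% of genes were called in these comparisons, in the same order. Far fewer genes were changed in the simulation, so its rates may not hold for the measured comparisons. For the list test, the proteasome list was shifted upward by 0.5 (log2). It was called upward in each comparison, and 0 other lists were called. The simulated spread was independent between genes, so this check could not show false calls of lists caused by correlated genes. Alternatives covered the background correction, the scaling between arrays (cyclic loess, median, 10 housekeeping genes), the filter, the probe rule, the variance model, array weights, the groups in the model, the authors' values, the methods' one-way test, a fold threshold, the replicate number as a block and leaving out each array. Slides could not be used as a block because no slide is named in the sources used here. The array numbers run by group, with controls first and resistant cells last. Any effect of array order or position that follows these numbers cannot be told apart from group.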

Results

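Gene expression was measured on Illumina HT-12 bead arrays in 12 samples of L428, an established Hodgkin lymphoma cell line. The samples formed 4 groups of 3: control cells, cells given 25 nM ixazomib for 24 h, cells given 71.25 nM ixazomib for 24 h, and L428 cells resistant to ixazomib. Ixazomib is an oral inhibitor of the proteasome, and the series title places the arrays in a study of lymphoma cell death that depends on MYC and on CHK1, the product of CHEK1. The labels give no dose for the resistant cells and do not say whether drug was in their medium at harvest. The description of 1 sample titled as 71.25 nM gives 25 nM instead, and the sample was kept in the group of its title. The series text mentions biological triplicates after describing the 25 nM treatment alone, and for the other groups separate cultures were assumed from numbered titles. The p-values measure only the spread between these samples, which may be technical. Mean signal per array ran from 343.5 to 400.5 in the controls, from 316.4 to 384 at 25 nM, from 342.3 to 353.8 at 71.25 nM and from 293.2 to 326.7 in resistant cells. Each array detected 17100 to 18785 of 47227 probes, the resistant arrays 18016 to 18785. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.13.

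Expression of 14953 genes was compared, and 7880 of them differed across the 4 groups at an adjusted p under 0.05 (10306 of 20414 probes). Arrays of 1 group correlated with r from 0.9898 to 0.9939, and arrays of different groups with r from 0.9503 to 0.9897. The first principal component, with 52.9% of the variance, ordered the groups as control, 25 nM, 71.25 nM and resistant, and the second component held 16.9%. The array numbers follow the same order of groups. On the first component the 71.25 nM arrays lay at 13.1 to 15.49 and the 25 nM arrays at -6.62 to -5.81. This argues against a 25 nM dose for the 71.25 nM sample whose description names it. Arrays were quantile normalized, so each rise or fall is relative to the other genes. Differences given without a unit are on the log2 scale. With this normalization the median of all genes against control was -0.002 at 25 nM, -0.006 at 71.25 nM and -0.02 in resistant cells. Scaling to housekeeping genes instead put the median of all genes at 0.12, 0.23 and 0.31 in that order, and at 0.10 between the doses. Median scaling put it at -0.14 in resistant cells against control and at -0.13 in resistant cells against 71.25 nM. An exact two-sided permutation test of 3 samples against 3 cannot go below p = 0.1, and chance alone leaves 10% of genes without overlap between such groups.

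After 24 h at 25 nM, genes of the heat shock response, of the proteasome and of the response to amino acid and oxidative stress rose, and genes of antigen presentation by MHC class II fell. HSPA6, a strictly stress-induced HSP70 chaperone, rose 9.46-fold (log2 difference 3.24 ± 0.12 SE, n = 3 per group, adjusted p = 1.29e-09). In controls HSPA6 lay near the detection limit (mean 5.05, detected on 2 of 3 arrays). Its mean signals before background correction were 117.5 in controls, 423.1 at 25 nM, 1738 at 71.25 nM and 2889 in resistant cells. The size of its folds against control therefore depends on the background correction. IL8, the gene of the chemokine CXCL8, rose 8.79-fold, GABARAPL1, which takes part in autophagosome formation, rose 8.16-fold and the cytokine gene IL9 rose 8.15-fold. The largest falls among genes with an official symbol were those of LRRC26, an accessory subunit of potassium channels (-2.66 ± 0.12 SE), KISS1R, the kisspeptin receptor (-2.26 ± 0.15 SE), SLC26A9, an anion transporter (-2.06 ± 0.15 SE), and SLC2A5, the fructose transporter (-2.02 ± 0.12 SE). In all, 4037 genes changed, 1993 up and 2044 down, and 385 of these by at least 2-fold. The groups of 6279 genes did not overlap.

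Of 40 genes of proteasome subunits and assembly factors, 27 rose and 1 fell at 25 nM (29 and 1 adjusted over the list alone). The list moved upward with an adjusted p of 7.92e-13, and of 0.00821 with an estimated correlation. PSMD2 (1.46 ± 0.11 SE), PSMC4 (1.41 ± 0.11 SE), PSMD6 (1.08 ± 0.10 SE) and ADRM1 (1.05 ± 0.10 SE) led, and PSMB5, which encodes the catalytic subunit that ixazomib binds, rose by 0.86 ± 0.10 SE (adjusted p = 2.38e-05). Of 27 heat shock and chaperone genes 18 rose (19 adjusted over the list alone, list adjusted p = 9.49e-13). HSPA1B rose by 2.74 and BAG3, a co-chaperone, by 1.70, while HSPA1A, not detected on any control array, was at least 3.86-fold higher (adjusted p = 1.63e-07). HSPA1A and HSPA1B are near-identical, as are HSPA6 and HSPA7, so which copy a probe read is uncertain. Of 24 genes of the ATF4 and integrated stress response 18 rose (19 adjusted over the list alone, list adjusted p = 9.49e-13), with the cystine transporter SLC7A11 at 1.95, DDIT3, the transcription factor CHOP, at 1.74 and CTH at 1.70. NRF2 and oxidative stress genes rose in 13 of 18 cases (15 adjusted over the list alone, list adjusted p = 4.64e-10). GCLM rose by 1.70 and HMOX1, heme oxygenase, by 1.59. Ubiquitin and autophagy genes rose in 11 of 20 cases (11 adjusted over the list alone, with 1 fall, list adjusted p = 1.59e-06). MAP1LC3B rose by 1.66 and SQSTM1 by 1.65. Of 24 genes of the unfolded protein response in the endoplasmic reticulum 11 rose and 1 fell (11 and 1 adjusted over the list alone, list adjusted p = 0.000601). DNAJB9 rose by 0.99.

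Of 29 NF-kB targets 13 rose and 4 fell at 25 nM (18 and 4 adjusted over the list alone, list adjusted p = 0.000189). Among them IL6 rose by 1.94 and TNF by 1.47, and CCL22, a chemokine of Hodgkin cells, fell by 1.58 on the log2 scale. Of 23 interferon response genes 11 rose (11 adjusted over the list alone, list adjusted p = 0.00154), IRF9 by 1.03. Of 13 MHC class II genes 8 fell (8 adjusted over the list alone, list adjusted p = 1.88e-05). HLA-DMB fell by 1.74 and HLA-DQB1 by 1.10 on the log2 scale. Immunoproteasome genes fell in 3 of 7 cases and rose in 1 (5 and 1 adjusted over the list alone, median -0.32, list adjusted p = 0.172, 0.0461 without the filter and up to 0.283 with an estimated correlation). CCL3L3 and CCL3, near-identical chemokine genes whose probes are uncertain in the same way, rose by 2.59 and 2.31. Apoptosis regulators rose in 8 of 25 cases and fell in 1 (8 and 1 adjusted over the list alone), with adjusted p = 0.00374 for the list and adjusted p = 0.086 with an estimated correlation. Of the p53 targets 5 of 22 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.463). GADD45A rose by 2.09 and CDKN1A, the cell cycle inhibitor p21, by 1.77. This list had a median of -0.01, 0.11 under the scaling that raised it most, and a mean of 0.12.

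MYC was 0.39 ± 0.11 SE higher at 25 nM (adjusted p = 0.0224), and this call was lost under median scaling (adjusted p = 0.204), with only the 2 groups in the model (adjusted p = 0.0586), with the mean of its probes (adjusted p = 0.0553), and without control array 1 (0.0552), control array 3 (0.0859), 25 nM array 4 (0.0778) or 25 nM array 6 (0.0832). CHEK1 differed by -0.18 ± 0.11 SE, which did not pass the test (adjusted p = 0.268). Of 34 MYC target and ribosome biogenesis genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, list adjusted p = 0.00144). NOP16 fell by 0.60 and SRM by 0.52 on the log2 scale. Cytosolic ribosomal protein genes fell in 14 of 70 cases (12 adjusted over the list alone), with adjusted p = 0.0101 for the list and adjusted p = 0.101 with an estimated correlation. Under cyclic loess scaling the list's adjusted p was 0.077. The S phase list (4 of 32 rose, 9 fell; 4 and 11 adjusted over the list alone, adjusted p = 0.0707) and the G2/M list (5 of 29 rose; 5 adjusted over the list alone, adjusted p = 0.0694) did not pass the test, but each passed under several alternatives. The S phase list passed downward without the filter (0.00923), without background correction (0.0476), under housekeeping scaling (0.0343), on the authors' values (0.0484), with the mean of the probes (0.0487) and without control array 3 (0.0308), and had up to 0.2, without control array 2. The G2/M list passed upward without the filter (0.00553), without background correction (0.0267), with an offset of 50 (0.046), on the authors' values (0.027), with a trend and robust prior (0.0421), with the mean of the probes (0.0496) and without 25 nM array 6 (0.0419), and had up to 0.313, under median scaling. Signals without background correction and the authors' values gave close counts of changed genes (4682 and 4685), so these alternatives are not separate checks. Scaling to housekeeping genes made 70.1% of the changed genes rises, against 49.4% with quantile normalization.

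**Figure D1:**
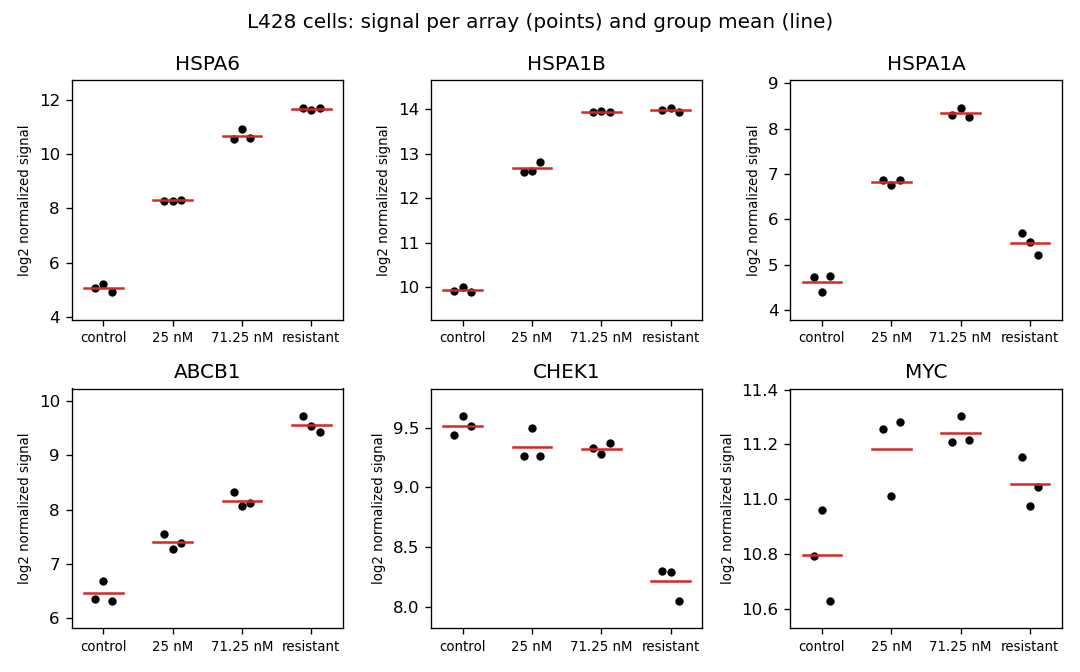
Log2 normalized signal of HSPA6, HSPA1B, HSPA1A, ABCB1, CHEK1 and MYC on each array (points) by group, with the group mean as a line and 3 arrays per group. HSPA6 rose from a mean of 5.05 in controls to 11.68 in resistant cells, while HSPA1A had a mean of 8.35 at 71.25 nM and 5.48 in resistant cells.

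At 71.25 nM for 24 h, heat shock, ATF4, unfolded protein and proteasome genes rose, and MHC class II genes and MYC targets fell. HSPA6 rose 49.4-fold (5.63 ± 0.12 SE, n = 3 per group, adjusted p = 2.74e-12), IL9 14-fold and GABARAPL1 12.8-fold. The normalized HSPA1B signal rose 16-fold, and its change here and in resistant cells may be larger if the top of the scale was compressed. HSPA1A was at least 11-fold higher (adjusted p = 4.13e-10), and the near-identical CCL3L3, CCL3 and CCL3L1 rose by 3.88, 3.68 and 3.49. The largest falls were those of LRRC26 (-3.81 ± 0.12 SE), SLC2A5 (-2.95 ± 0.12 SE), KISS1R (-2.67 ± 0.15 SE) and the near-identical FRG2B and FRG2 (-2.65 and -2.49). CYP4Z2P, which shares sequence with CYP4Z1, differed by -2.56 on its brightest probe and by -0.08 on its other probe. In all, 5840 genes changed, 2902 up and 2938 down, 896 of them by at least 2-fold, and the groups of 7199 genes did not overlap.

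Of 27 heat shock and chaperone genes 24 rose at 71.25 nM (24 adjusted over the list alone, list adjusted p = 7.4e-16). DNAJB1, an HSP40 partner of HSP70, rose by 3.07. The ATF4 list rose in 21 of 24 cases (21 adjusted over the list alone, list adjusted p = 1.32e-14), DDIT3 by 2.97 and SESN2 by 2.86, and the unfolded protein list in 18 of 24, with 1 fall (18 and 1 adjusted over the list alone, list adjusted p = 1.77e-06), DNAJB9 by 2.12 and HSPA5, the chaperone BiP, by 1.49. Proteasome genes rose in 29 of 40 cases and fell in 1 (33 and 2 adjusted over the list alone, list adjusted p = 2.56e-09), with PSMB5 at 0.93 ± 0.10 SE. Of 18 NRF2 genes 13 rose (14 adjusted over the list alone, list adjusted p = 3.66e-07), HMOX1 by 2.29, and of 20 ubiquitin and autophagy genes also 13 (13 adjusted over the list alone, with 2 falls, list adjusted p = 8.13e-06), MAP1LC3B by 2.30. Of 25 apoptosis regulators 12 rose and 3 fell (12 and 3 adjusted over the list alone), with adjusted p = 0.0063 for the list and adjusted p = 0.0967 with an estimated correlation. PMAIP1, the BH3-only protein NOXA, rose by 1.24 and BCL2L11, the BH3-only protein BIM, by 1.16.

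Of 13 MHC class II genes 11 fell at 71.25 nM (11 adjusted over the list alone, list adjusted p = 1.99e-06). HLA-DMB fell by 2.20 and HLA-DQB1 by 1.91 on the log2 scale. Immunoproteasome genes fell in 4 of 7 cases (5 adjusted over the list alone, median -0.33, list adjusted p = 0.107, 0.0165 without the filter, 0.028 under housekeeping scaling and up to 0.225 with an estimated correlation). Interferon response genes rose in 13 of 23 cases and fell in 2 (13 and 3 adjusted over the list alone, list adjusted p = 0.00813). IRF9 rose by 1.24 and IFIT2 by 1.20. CCL22 fell by 2.13 and CCL17, also a chemokine of Hodgkin cells, by 1.19 on the log2 scale. The Hodgkin cell marker list had 6 rises and 6 falls among 19 (7 and 7 adjusted over the list alone, list adjusted p = 0.988), with a median of 0.13 that was -0.01 under another scaling and a mean of -0.10. The NF-kB list, with 10 rises and 6 falls of 29 (10 and 6 adjusted over the list alone, list adjusted p = 0.255), had a median of 0.09 that was -0.07 under another scaling. B cell markers fell in 3 of 12 cases (3 adjusted over the list alone, list adjusted p = 0.117). The kinase gene BLK fell by 1.46 and the transcription factor gene SPIB by 1.10 on the log2 scale, with a list median of -0.20 that was 0.07 under another scaling. ABCB1, the drug efflux pump P-glycoprotein, rose by 1.71 ± 0.13 SE, and its list of 6 measured efflux genes had 3 rises and 2 falls (3 and 2 adjusted over the list alone, list adjusted p = 0.72).

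MYC was 0.45 ± 0.11 SE higher at 71.25 nM (adjusted p = 0.00691), a call lost under median scaling (adjusted p = 0.177), and CHEK1 differed by -0.19 ± 0.11 SE (adjusted p = 0.184). Of 34 MYC targets 16 fell and 1 rose (21 and 2 adjusted over the list alone, list adjusted p = 0.000172). SRM fell by 1.23 and CAD by 0.94 on the log2 scale. The S phase list had 13 falls and 5 rises among 32 (15 and 5 adjusted over the list alone, list adjusted p = 0.0989, 0.0124 without the filter, 0.023 under housekeeping scaling and up to 0.201 without control array 2), with GINS2, of the replicative helicase, lower by 1.16. The G2/M list had 6 rises and 5 falls among 29 (6 and 5 adjusted over the list alone, list adjusted p = 0.932), TPX2 at 0.92 and AURKB at -0.71. Its median of -0.04 became 0.11 under another scaling. Oxidative phosphorylation genes fell in 11 of 34 cases and rose in 1 (11 and 1 adjusted over the list alone), with adjusted p = 0.0448 for the list and adjusted p = 0.0833 with an estimated correlation. The oxidative phosphorylation call was also lost under cyclic loess (0.0547), under the stricter detection filter (0.0591), with only the 2 groups in the model (0.0582), and without array 1 (0.0612), 2 (0.0523), 3 (0.0533), 4 (0.0662), 6 (0.0662), 8 (0.0762), 10 (0.0525), 11 (0.0624) or 12 (0.0692). Scaling to housekeeping genes made 75.8% of the changed genes rises, against 49.7% with quantile normalization.

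Set directly against each other, the 71.25 nM and 25 nM samples differed in 877 genes, 446 higher and 431 lower at 71.25 nM, 50 of them by at least 2-fold, and the groups of 4359 genes did not overlap. HSPA6 was 2.38 ± 0.12 SE higher at the higher dose (n = 3 per group, adjusted p = 2.61e-07), DNAJB1 1.71 ± 0.12 SE and SESN2, a stress-induced sestrin, 1.71 ± 0.12 SE. RN5S9, annotated as a 5S ribosomal RNA gene, rose by 2.06 ± 0.14 SE. LSP1, a leukocyte actin-binding protein, fell by 1.48 on the log2 scale on its brightest probe, while its other probes differed by -0.88, 0.06 and -1.22, and the near-identical FRG2 and FRG2B fell by 1.65 and 1.55 on the log2 scale.

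Heat shock genes were higher at 71.25 nM than at 25 nM in 13 of 27 cases (19 adjusted over the list alone, list adjusted p = 8.49e-17), ATF4 genes in 11 of 24 (18 adjusted over the list alone, list adjusted p = 1.09e-15) and unfolded protein genes in 7 of 24 (11 adjusted over the list alone, list adjusted p = 5.62e-06). With an estimated correlation the heat shock and ATF4 lists each had an adjusted p of 0.00332 and the unfolded protein list 0.00652. DDIT4 rose by 1.44, DDIT3 by 1.23 and HSPA5 by 1.02. Limma called 0 of 40 proteasome genes between the doses, and 1 was higher and 2 were lower at an unadjusted p under 0.05; PSMB5 differed by 0.07 ± 0.10 SE (adjusted p = 0.743). The list's median was -0.03, and 0.04 under another scaling (list adjusted p = 0.551). BCL2L11 rose by 0.85 while BCL2L1, which encodes the survival protein BCL-XL, fell by 0.87 on the log2 scale. MYC differed by 0.06 ± 0.11 SE (adjusted p = 0.82) and CHEK1 by -0.02 ± 0.11 SE (adjusted p = 0.95).

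Further lists passed the test between the doses and lost the call with an estimated correlation. MHC class II genes fell in 4 of 13 cases (6 adjusted over the list alone, list adjusted p = 0.000136, adjusted p = 0.0632 with an estimated correlation). HLA-DQB1 fell by 0.81 on the log2 scale. G2/M genes fell in 2 of 29 cases (7 adjusted over the list alone, with 1 rise, list adjusted p = 0.00957, adjusted p = 0.136 with an estimated correlation). PLK1, a mitotic kinase, fell by 0.62 on the log2 scale. The NF-kB list had 8 falls and 3 rises among 29 (11 and 4 adjusted over the list alone, list adjusted p = 0.0273, adjusted p = 0.0661 with an estimated correlation), CCL17 at -0.85 and IL6 at 0.91. Its median of -0.08 was 0.02 under another scaling. MYC targets (1 fall of 34, SRM at -0.70; 1 adjusted over the list alone), cholesterol synthesis genes (1 rise of 20; 6 adjusted over the list alone) and oxidative phosphorylation genes (1 fall of 34; 1 adjusted over the list alone) had list adjusted p values of 0.0276, 0.0273 and 0.0273, each with adjusted p = 0.0661 with an estimated correlation. These calls were also lost in part with 1 array left out. Without 25 nM array 4 the NF-kB, MYC target, cholesterol and oxidative phosphorylation lists each had an adjusted p of 0.0625. Without 71.25 nM array 8 the G2/M, NF-kB and cholesterol lists had 0.0698, and the MYC target and oxidative phosphorylation lists 0.0768. The MYC target list had 0.0717 without 71.25 nM array 7, and the oxidative phosphorylation list 0.0757 without 25 nM array 5 and 0.0511 without resistant array 12. Under median scaling the cholesterol list had an adjusted p of 0.0571, and under housekeeping scaling the oxidative phosphorylation list had 0.0543. Without 25 nM array 4 the number of lists called fell from 9 to 5, and without 71.25 nM array 8 to 4. The count of genes was 454, 489 and 373 without 25 nM array 4, 5 or 6, 455 and 442 without 71.25 nM array 7 or 9, 1774 without background correction, 1575 with a larger offset, 1775 on the authors' values, 1529 with a trend in the prior variance, and 400 under median scaling. Scaling to housekeeping genes made 79.8% of the differing genes higher at 71.25 nM, against 50.9% with quantile normalization.

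Resistant cells differed from controls by high levels of heat shock genes, interferon response genes, IL8 and ABCB1, and by low levels of cell cycle and DNA repair genes. HSPA6 was 98.7-fold higher (6.63 ± 0.12 SE, n = 3 per group, adjusted p = 1.52e-13), IL8 50.8-fold (5.67 ± 0.10 SE), IL9 35.3-fold (5.14 ± 0.12 SE) and RARRES3, an acyltransferase gene, 17.4-fold (4.12 ± 0.15 SE). As at both doses, the HSPA6 fold starts from controls near the detection limit. ABCB1 was 8.57-fold higher (3.10 ± 0.13 SE, adjusted p = 5.31e-10), and its other probe was higher by 1.78. CHEK1 fell by 1.31 on the log2 scale (SE 0.11, adjusted p = 3.63e-07). MYC differed by 0.26 ± 0.11 SE, which did not pass the test (adjusted p = 0.0781), although it did under several alternatives with adjusted p between 0.0153 and 0.0383.

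The other genes with the largest differences in resistant cells included HSPA7 at 4.52, HSPA1B at 4.05, RN5S9 at 4.01, and the near-identical CCL3, CCL3L3 and CCL3L1 at 4.42, 4.42 and 4.32. Among the falls, LRRC26 was at -3.84 ± 0.12 SE, NCALD, a neuronal calcium sensor, at -2.98 ± 0.10 SE, KISS1R at -2.98 ± 0.15 SE and E2F2, a transcription factor of S phase entry, at -2.66 ± 0.14 SE. The near-identical FRG2B and FRG2 were at -3.50 and -3.14, and CYP4Z1 was at -2.94. In all, 7048 genes changed, 3440 up and 3608 down, 1512 of them by at least 2-fold, and the groups of 8038 genes did not overlap. The share of rises was 48.8%, against 30.5% under median scaling and 74.8% under housekeeping scaling.

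In resistant cells 27 of 29 G2/M genes fell (28 adjusted over the list alone, list adjusted p = 9.34e-15). With an estimated correlation this list's adjusted p was 0.00188. The mitotic kinase genes AURKB fell by 2.19 and PLK1 by 2.05 and the cyclin gene CCNA2 by 2.03 on the log2 scale. Of 32 S phase genes 26 fell and 1 rose (26 and 1 adjusted over the list alone, list adjusted p = 3.33e-11). GINS2 fell by 1.99 and TYMS, thymidylate synthase, by 1.98 on the log2 scale. DNA damage and checkpoint genes fell in 20 of 28 cases and rose in 2 (20 and 2 adjusted over the list alone, list adjusted p = 1.88e-05), among them BRCA1 by 1.75 on its brightest probe, FANCD2 by 1.63 and TIMELESS by 1.53 on the log2 scale. Another probe of BRCA1 differed by 0.11. MYC targets fell in 29 of 34 cases and rose in 1 (30 and 1 adjusted over the list alone, list adjusted p = 9.17e-08). SRM fell by 1.45, CAD by 1.40 and ODC1, ornithine decarboxylase, by 1.28 on the log2 scale. Mean signals of the resistant arrays lay at 293.2 to 326.7, and 1 other array, at 25 nM, lay in that range at 316.4.

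Of 27 heat shock genes 26 rose in resistant cells (26 adjusted over the list alone, list adjusted p = 1.19e-14). NRF2 genes rose in 16 of 18 cases (16 adjusted over the list alone, list adjusted p = 1.64e-08), HMOX1 by 3.20, and ATF4 genes in 18 of 24, with 1 fall (18 and 1 adjusted over the list alone, list adjusted p = 4.6e-10), DDIT3 by 3.52 and DDIT4 by 3.25. Proteasome genes rose in 31 of 40 cases and fell in 3 (32 and 3 adjusted over the list alone, list adjusted p = 6.33e-09), with PSMB5 at 0.84 ± 0.10 SE. Unfolded protein genes rose in 17 of 24 cases and fell in 1 (18 and 1 adjusted over the list alone, list adjusted p = 1.88e-05), and ubiquitin and autophagy genes rose in 13 of 20 and fell in 1 (14 and 1 adjusted over the list alone, list adjusted p = 3.81e-06). Apoptosis regulators rose in 15 of 25 cases and fell in 1 (15 and 1 adjusted over the list alone, list adjusted p = 0.000335). Of 24 glycolysis and hypoxia genes 14 rose and 5 fell (14 and 5 adjusted over the list alone, list adjusted p = 0.00511, and 0.0516 under housekeeping scaling). SLC2A3, a glucose transporter, rose by 2.35. Of 22 p53 targets 7 rose and 3 fell (7 and 3 adjusted over the list alone), CDKN1A by 3.38. The list's adjusted p = 0.0371 became adjusted p = 0.0697 with an estimated correlation, 0.0603 under median scaling, 0.0804 under housekeeping scaling and 0.0503 without control array 1.

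Interferon response genes rose in 19 of 23 cases in resistant cells (19 adjusted over the list alone, list adjusted p = 4.6e-10). IRF9 rose by 2.52, IRF7 by 2.13 and IFI44 by 2.11. NF-kB targets rose in 16 of 29 cases and fell in 5 (16 and 6 adjusted over the list alone, list adjusted p = 0.000394). IL6 rose by 3.36 and ICAM1 by 2.64. MHC class I genes rose in 9 of 12 cases and fell in 1 (9 and 1 adjusted over the list alone, list adjusted p = 0.00339, adjusted p = 0.0913 with an estimated correlation). HLA-E rose by 1.27. MHC class II genes fell in 7 of 13 cases and rose in 1 (8 and 1 adjusted over the list alone, list adjusted p = 0.0211, adjusted p = 0.112 with an estimated correlation). HLA-DQB1 fell by 1.93 on the log2 scale. Myeloid markers rose in 4 of 6 cases (4 adjusted over the list alone), CD68, a lysosomal protein, by 2.36. The list's adjusted p = 0.031 became adjusted p = 0.102 with an estimated correlation, 0.0518 without the filter and 0.0554 without control array 1. Of 5 measured T cell markers 2 rose (2 adjusted over the list alone, list adjusted p = 0.0679). GATA3 rose by 0.85. The list passed upward under median scaling (0.0394), under housekeeping scaling (0.0491), under the stricter detection filter (0.0428) and without resistant array 11 (0.0463), and had 0.261 without the filter. The Hodgkin cell markers, with 9 rises and 5 falls among 19 (9 and 5 adjusted over the list alone, list adjusted p = 0.123, 0.0356 without the filter and up to 0.493 under housekeeping scaling), had a median of 0.21 that was -0.15 under another scaling. CD274, the immune checkpoint ligand PD-L1, was at least 2.19-fold higher, and CCL22 at least 4.3-fold lower. The immunoproteasome list had 2 rises among 7 (2 adjusted over the list alone, list adjusted p = 0.0538), with TAP1, a peptide transporter, at 1.20, and its median of 0.25 was -0.14 under median scaling. It did not pass under median scaling or with an estimated correlation (adjusted p = 0.127). It passed upward without the filter (0.0059), without background correction (0.0332) and, as no separate check, on the authors' values (0.0331). The list also passed with an offset of 50 (0.0442), with a trend and robust prior (0.0404) and without resistant array 11 (0.0416).

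Histone genes rose in 12 of 20 cases and fell in 4 in resistant cells (12 and 4 adjusted over the list alone, list adjusted p = 0.00392, adjusted p = 0.0637 with an estimated correlation). HIST1H4H rose by 2.33. Oxidative phosphorylation genes fell in 15 of 34 cases and rose in 4 (15 and 5 adjusted over the list alone, list adjusted p = 0.014). NDUFB10 fell by 1.28 on the log2 scale. Cytosolic ribosomal protein genes fell in 22 of 70 cases and rose in 2 (22 and 2 adjusted over the list alone, list adjusted p = 0.0174, adjusted p = 0.0967 with an estimated correlation), and their median of -0.11 was 0.03 under housekeeping scaling and 0.01 under cyclic loess, where the list's adjusted p was 0.711. Metallothionein genes rose in 4 of 6 cases and fell in 1 (4 and 1 adjusted over the list alone, list adjusted p = 0.0827). MT2A rose by 0.78. Cholesterol synthesis genes rose in 3 of 20 cases and fell in 5 (3 and 5 adjusted over the list alone, list adjusted p = 0.787). EBP fell by 1.09 on the log2 scale, and the list had a median of -0.03 that was 0.24 under another scaling. The drug efflux list, with 3 rises and 2 falls among 6 (3 and 2 adjusted over the list alone, list adjusted p = 0.43), included MVP at 1.55 and ABCA3 at -1.47. B cell markers rose in 2 of 12 cases and fell in 4 (2 and 4 adjusted over the list alone, list adjusted p = 0.335), with a median of -0.11 that was 0.32 under another scaling. Of the stromal and epithelial markers 2 were measured, and ACTA2 rose by 1.27 (1 adjusted over the list alone, list adjusted p = 0.203).

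**Figure D2:**
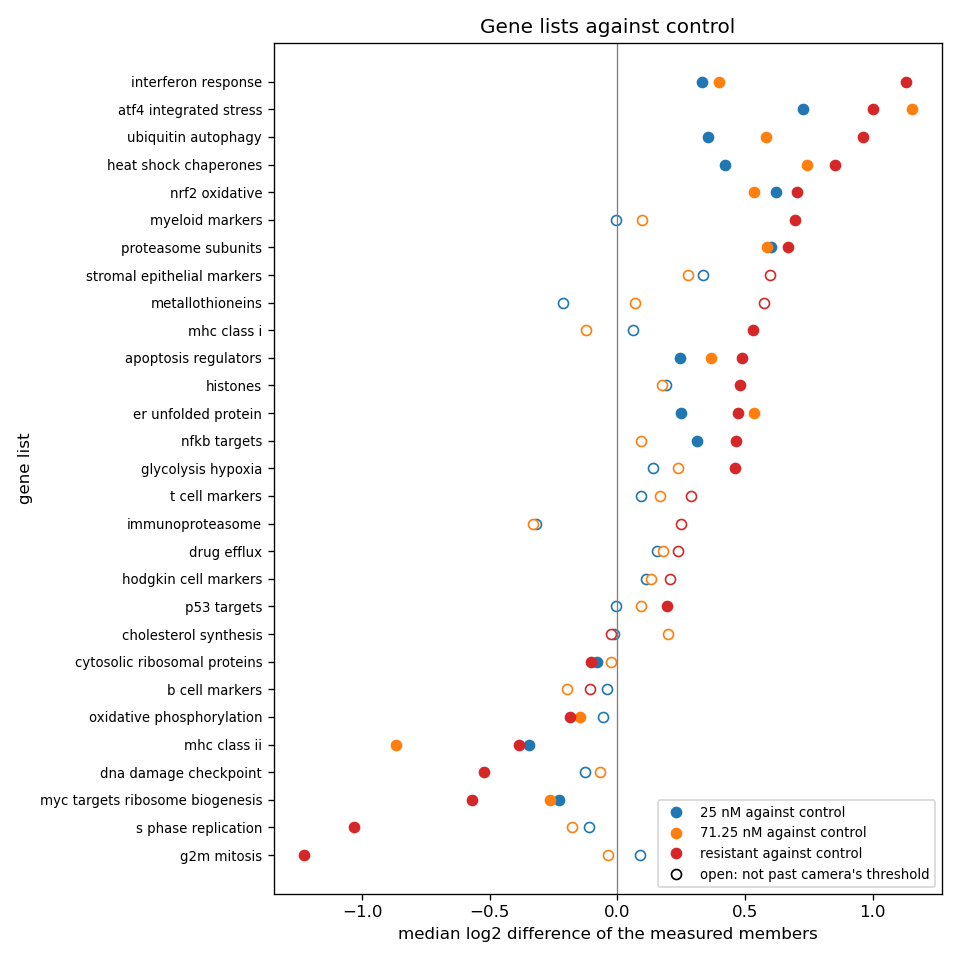
Median log2 difference from control of the measured members of each of 29 gene lists at 25 nM, at 71.25 nM and in resistant cells, 3 arrays per group, with filled points for lists past the adjusted p threshold of 0.05 in camera and open points for the others. The G2/M list had medians of 0.09, -0.04 and -1.23 in that order, with its 71.25 nM median at 0.11 under another scaling, and the interferon list 0.33, 0.40 and 1.13.

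Set directly against cells given 71.25 nM for 24 h, resistant cells had higher interferon response and antigen presentation genes and lower cell cycle genes. UBD, an interferon-inducible ubiquitin-like modifier not detected on any 71.25 nM array, was at least 10-fold higher (n = 3 per group, adjusted p = 1.46e-08). RARRES3 was higher by 2.78 ± 0.15 SE, TMEM140 by 2.76 ± 0.18 SE, IDO1, a tryptophan-degrading enzyme, by 2.60 ± 0.14 SE, and GBP1, an interferon-induced GTPase, by 2.35 ± 0.14 SE. The largest falls were those of HSPA1A (-2.87 ± 0.14 SE, adjusted p = 3.34e-08), CCNA2 (-2.13 ± 0.12 SE), RRM2, a ribonucleotide reductase subunit (-1.96 ± 0.13 SE), and CDCA3 (-1.93 ± 0.11 SE). In all, 3223 genes differed, 1688 higher and 1535 lower in resistant cells, 363 of them by at least 2-fold, and the groups of 5666 genes did not overlap. The share higher was 52.4%, against 27.0% under median scaling.

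G2/M genes were lower in resistant cells than at 71.25 nM in 27 of 29 cases (29 adjusted over the list alone, list adjusted p = 1.6e-30) and S phase genes in 28 of 32 (30 adjusted over the list alone, list adjusted p = 3.36e-22). With an estimated correlation the adjusted p of the G2/M list and of the S phase list was 0.000257. DNA damage and checkpoint genes fell in 17 of 28 cases (18 adjusted over the list alone, list adjusted p = 4.08e-10). CDC25C fell by 1.56 and CHEK1 by 1.11 on the log2 scale. MYC targets fell in 12 of 34 cases (13 adjusted over the list alone, list adjusted p = 6.59e-05), ODC1 by 1.13 on the log2 scale, while MYC itself differed by -0.19 ± 0.11 SE (adjusted p = 0.288). Interferon response genes rose in 19 of 23 cases (20 adjusted over the list alone, list adjusted p = 3.91e-14). OAS2 rose by 1.79 and IRF7 by 1.53. MHC class I genes rose in 8 of 12 cases (9 adjusted over the list alone, list adjusted p = 1.98e-06), HLA-E by 1.02, MHC class II genes in 7 of 13 (8 adjusted over the list alone, with 1 fall, list adjusted p = 0.000634), CD74 by 0.96, and immunoproteasome genes in 6 of 7 (6 adjusted over the list alone, list adjusted p = 1.73e-05), PSMB9 by 1.07. The immunoproteasome median of 0.75 against 71.25 nM stood beside medians from control of -0.33 at 71.25 nM and 0.25 in resistant cells (-0.14 under median scaling), so lower values at 71.25 nM were part of this difference. The MHC class II median of 0.46 stood beside medians from control of -0.87 at 71.25 nM and -0.38 in resistant cells. On balance the class II rise was thus a smaller fall from control. NF-kB targets rose in 17 of 29 cases (18 adjusted over the list alone, with 2 falls, list adjusted p = 8.64e-07), ICAM1 by 1.63, and Hodgkin cell markers in 9 of 19 (9 adjusted over the list alone, with 3 falls, list adjusted p = 0.00181), CD274 by 1.22. Myeloid markers rose in 3 of 6 cases (4 adjusted over the list alone, list adjusted p = 0.00539, adjusted p = 0.0578 with an estimated correlation). CSF1R rose by 1.19.

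Heat shock genes were higher in resistant cells than at 71.25 nM in 8 of 27 cases and lower in 1 (9 and 1 adjusted over the list alone, list adjusted p = 0.00539, adjusted p = 0.103 with an estimated correlation, and 0.0674 under median scaling). HSPA6 rose by 1.00 and HSPB1 by 0.77, and HSPA1A was the member that fell. ATF4 genes rose in 4 of 24 cases and fell in 7 (4 and 8 adjusted over the list alone, list adjusted p = 0.467), WARS at 1.35 and CTH at -0.97, with a list median of -0.05 that was 0.02 under another scaling. NRF2 genes rose in 8 of 18 cases (8 adjusted over the list alone, list adjusted p = 0.00236), HMOX1 by 0.91. ABCB1 rose by 1.39 ± 0.13 SE (adjusted p = 6.33e-06), and BCL2L11 fell by 1.10 on the log2 scale. Apoptosis regulators rose in 5 of 25 cases and fell in 1 (5 and 1 adjusted over the list alone, list adjusted p = 0.0403, adjusted p = 0.16 with an estimated correlation). This call was also lost under median scaling (0.233), under housekeeping scaling (0.139), with the mean of the probes (0.29), and without 71.25 nM array 7 (0.0683) or 9 (0.0747) or resistant array 12 (0.072). Histone genes rose in 9 of 20 cases and fell in 2 (9 and 3 adjusted over the list alone, list adjusted p = 0.000634). HIST1H2BD rose by 1.40. Cholesterol synthesis genes fell in 5 of 20 cases and rose in 1 (5 and 1 adjusted over the list alone, list adjusted p = 0.027, adjusted p = 0.0601 with an estimated correlation). EBP fell by 0.50 on the log2 scale. Glycolysis and hypoxia genes rose in 7 of 24 cases (7 adjusted over the list alone, with 3 falls, list adjusted p = 0.0156, adjusted p = 0.074 with an estimated correlation), with a median of 0.17 that was -0.05 under median scaling, where the list's adjusted p was 0.0812, against 0.0712 under housekeeping scaling. Proteasome genes rose in 3 of 40 cases and fell in 1 in limma (list adjusted p = 0.289). Adjusted over the list alone 0 did, against 7 rises and 2 falls at an unadjusted p under 0.05. PSMB5 was at -0.09 ± 0.10 SE (adjusted p = 0.561), and the list's median of 0.06 was -0.14 under another scaling.

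Log2 differences from control were compared across genes between the treated and resistant groups, which shared the same 3 controls; genes are not independent replicates. The 25 nM and 71.25 nM differences correlated with Pearson's r = 0.883 and Spearman's rho = 0.84, those of 25 nM and resistant cells with 0.747 and 0.702, and those of 71.25 nM and resistant cells with 0.813 and 0.769. Unchanged groups simulated against the same controls gave r = 0.499, rho = 0.475 and a covariance of 0.0104, against observed covariances of 0.185, 0.193 and 0.278. Between the 25 nM and 71.25 nM lists, 1725 genes rose in both, 1762 fell in both and 2 moved in opposite directions. Independent lists of these sizes would share 387 and 402. Between 71.25 nM and resistant cells, 2222 rose and 2196 fell in both, 113 moved in opposite directions, and independent lists would share 668 and 709. Between 25 nM and resistant cells, 1589 rose and 1619 fell in both, 100 moved in opposite directions, and independent lists would share 458 and 493. With 3 controls no split leaves 2 in each part, so part of the excess may come from the shared controls.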

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

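The comparison with random lists, the test of 24 h of drug alone, the test for T or myeloid cells and the test of the heat shock class were chosen only after the results were seen.

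Probes without a gene name, which no comparison of genes used, differed from control in 100 cases at 25 nM, 139 at 71.25 nM and 182 in resistant cells, of 1195 tested. Of these, 23, 34 and 73 rose. Among named genes a larger share was called, 27%, 39.06% and 47.13% in the same order. Probes whose symbol had turned into a date counted as unnamed, so some may belong to known genes.

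Cell cycle genes were lower in resistant cells than in controls. Under the scaling that weakened it most, the median of S phase and G2/M members lay at -1.16 (log2) relative to all genes. Median and housekeeping scaling cannot differ from each other in this measure, since each adds a constant per array, so they are not separate checks. Without subtracting the median of all genes, the S phase median was -1.371 to -0.919 over the scalings. That of G2/M was -1.476 to -1.024, and both argue against the scaling. Against 10000 random lists matched on mean signal both lists lay at percentile 0. The random medians ran from -0.463 to 0.471 for S phase and from -0.555 to 0.509 for G2/M. Genes of like signal thus did not fall in this way, which argues against the dimmer resistant arrays. The lists were taken up because of their fall, so the percentile is no further support for the fall itself. At 71.25 nM the same members had a median of -0.078 against control, which argues against 24 h of drug at that dose as the whole cause. Long drug exposure, selection and slower growth of resistant cells may each underlie it and were not tested.

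Interferon response genes were higher in resistant cells than at 71.25 nM. Under the weakest scaling their median stayed 0.66 above that of all genes, a measure in which median and housekeeping scaling likewise cannot differ from each other. Without subtracting the median of all genes, the list's median was 0.529 to 0.715 over the scalings, which argues against scaling. The lowest resistant array stood 0.71 above the 71.25 nM mean, which argues against 1 aberrant array. Of 11 abundant T cell and myeloid transcripts, 0 were detected on every resistant array and on no 71.25 nM array; LYZ and CD14 were detected on all arrays of both groups, at 5.93 and 5.09 (log2) at 71.25 nM and 5.90 and 5.47 in resistant cells, and LCK on 2 resistant arrays. Myeloid markers rose in 3 of 6 cases (median 0.60, list adjusted p = 0.00539, adjusted p = 0.0578 with an estimated correlation) and T cell markers in 2 of 5 (median 0.33, list adjusted p = 0.122, with median 0.76 and adjusted p = 0.0476 under the stricter detection filter and 0.374 without the filter), but CD3D, CD3E, TYROBP, FCER1G, S100A8 and S100A9, abundant in such cells, were detected on no array, which argues against such cells as the source. A state of the resistant cells may underlie the pattern, as a hypothesis, and resistance cannot be separated from drug exposure here because the labels give none for these cells.

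HSPA1A was lower in resistant cells than at 71.25 nM (5.48 against 8.35, log2) while HSPA1B was not (13.99 against 13.94). Under the processing alternative that weakened it most HSPA1A still differed by -1.68, which argues against background correction and normalization, and the other heat shock genes had a median of 0.18, which argues against a fall of the class. HSPA1B reached 72.8% of the brightest probe of its array, so a compressed top of the scale cannot be told apart from an equal level. A sequence difference under the HSPA1A probe in resistant cells may also give the pattern and was not tested, since the arrays hold no sequence.

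For the 7880 genes that differed across the groups, 1 of 100 splits of the 12 samples, the real one, gave as many. The highest other split gave 3211, which argues against a chance division of these samples. If the replicates are technical, the splits measure how repeatable the arrays were. They then cannot exclude chance differences between single cultures. The splits of 3 samples against 3 are too few for a share under 0.05: the real split gave 4037 genes at 25 nM, 5840 at 71.25 nM, 7048 in resistant cells, 877 between the doses and 3223 between resistant cells and 71.25 nM. The highest other of the 10 splits gave 0 genes in limma in each case, and 675, 959, 596, 831 and 869 genes at an unadjusted p under 0.05.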

How the results depend on the processing

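The authors' values with the replicate number as a block, and those without the 71.25 nM sample whose description names another dose, were chosen after seeing the data. Of 531 called results for named genes, 457 kept their direction and their call under every alternative that gave a value, and of 70 called lists 48 did. Named genes were picked largely by size, so their share may overstate stability. Of all called genes, median scaling also called 2854 of 4037 at 25 nM and 4751 of 5840 at 71.25 nM. It called 5600 of 7048 in resistant cells, 383 of 877 between the doses and 2276 of 3223 against 71.25 nM. Housekeeping scaling called 3248, 4538, 5631, 651 and 2744 of them, in that order. PSMB9 reversed in resistant cells against control with the mean of its probes (-0.012, adjusted p = 0.936; its probes differ), and the Hodgkin marker list at 71.25 nM, with a median of 0.13, was called downward by fry. Genes differing between the doses numbered 1774 without background correction, 1575 with an offset of 50, 400 under median scaling, 1775 on the authors' values and 1529 with a trend and robust prior; leaving out 1 array gave 373 to 956. Lists called between the doses numbered 14 without the filter, 3 with an estimated correlation and 4 to 10 with 1 array left out. By fry, which does not compare a list with other genes, 24, 24, 17 and 26 lists were called at 25 nM, at 71.25 nM, between the doses and in resistant cells against 71.25 nM. A 2-fold threshold, which is stricter by construction, left 385, 896, 1512, 50 and 363 genes in the 5 comparisons. Signals without background correction and the authors' values gave close counts, 4682 and 4685 genes at 25 nM and 7260 and 7253 in resistant cells. Results on the 1 are therefore no separate check of the other. The correlations of 25 nM and of 71.25 nM with resistant cells were 0.776 and 0.833 without background correction and on the authors' values. They were 0.776 and 0.83 on the authors' values without the sample whose description names another dose. Over genes called in either comparison the 3 correlations were 0.923, 0.782 and 0.835. Except where stated, the cause was not tested. Arrays detected 36.2% to 39.8% of probes, and probes detected on fewer than 3 arrays were not tested except without the filter.

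Replicate numbers of the labels did not pair the samples: 2 of 18 same-number pairs of the authors' values correlated above 0.1 (range -0.286 to 0.161), and 3 of 12 samples correlated best with their own number. With the replicate number as a block on the authors' values, 1623 genes differed between the doses and the correlations were 0.776 and 0.833; without the block the authors' values gave 1775. A slide block was not run, since no slide is named in the sources used here.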

Other observations

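All tests here were planned.

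Among gene groups at the 2 doses not yet described, cholesterol synthesis genes rose in 8 of 20 cases and fell in 5 at 71.25 nM (9 and 5 adjusted over the list alone, list adjusted p = 0.356). Glycolysis and hypoxia genes rose in 11 of 24 cases and fell in 4 at 71.25 nM (12 and 6 adjusted over the list alone, list adjusted p = 0.0864). The list passed upward without the filter (0.0165) and had 0.177 with an estimated correlation. SLC2A3 rose by 1.93. Histone genes rose in 8 of 20 cases and fell in 3 (8 and 3 adjusted over the list alone, list adjusted p = 0.247). DNA damage and checkpoint genes rose in 5 of 28 cases and fell in 6 (5 and 7 adjusted over the list alone, list adjusted p = 0.839), with a median of -0.07 that was 0.12 under another scaling. Of the drug efflux genes, ABCC4 fell by 0.91 and 0.93 on the log2 scale at 25 and 71.25 nM and ABCA3 by 0.62 and 1.07, while MVP, the major vault protein, rose by 0.97 and 0.75.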
